A study of Mus musculus and Homo sapiens with 56 samples.

How the data were processed

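The labels describe poly(A) RNA sequenced from 56 samples in 16 groups. Cell RNA came from IMR-90 fibroblasts with ER:Ras, and the cell groups without a named target carried a control siRNA. Mouse RNA came from liver and kidney after intraperitoneal injections 2 to 3 times a week for 1 month, in corn oil. Libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols, which state no strand protocol. Reads of a gene and of an overlapping or antisense neighbour therefore cannot be told apart here, and genes with near-identical copies are uncertain.

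Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0 and quantified with RSEM 1.3.1, and the builds were hg19 for human and mm10 for mouse. The aligner is not given in the sources used here. The deposited expected counts are RSEM's estimates of reads per RefSeq gene, shared out between transcripts and copies where reads matched several, and were not normalized. The deposited TPM values are RSEM's transcript shares within a library. Per the file headers the FPKM values beside them are RSEM's fragments scaled by gene length and library size; FPKM was not used in any result. Each library covered 26334 human or 24411 mouse genes. Of the expected counts above 0, 16.7 to 25.9% were not whole, at the 2 decimals given, in the cells, 4.94 to 5.56% in liver and 13.1 to 13.5% in kidney. They were rounded to whole numbers before testing.

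Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates are separate cultures or animals, so p-values measure the spread between these samples, which may be technical. No library pair of a group held the same values, and every pair differed by more than counting noise (chi-square per degree of freedom of at least 2.98).

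The tests, the groups in each fit, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Each of 4 sets of libraries (the 8-day cells, the 6-day cells, liver and kidney) was fitted with all its groups, so that they share an estimate of the spread. Genes passed filterByExpr of edgeR with a minimum count of 10, libraries were scaled by TMM, and edgeR's quasi-likelihood test with robust estimation was used, two-sided, with Benjamini-Hochberg adjustment within a comparison at 5% and no limit on the fold change. There were 16 comparisons, and 4 differences between effects (6 against 8 days, and kidney against liver for age, DCV and JQ1) tested as interactions. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Mouse positions are those of GENCODE M21, which holds 336 of 345 named mouse genes; no human annotation was used here.

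In all, 19 human and 39 mouse gene lists of pathways and of markers of other cell types were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 3 tested members were left out. Camera with an estimated correlation and fry were alternatives; fry asks whether a list moves one way and does not compare it with other genes. Lists of genes at least 2-fold higher or lower in senescence were taken from the other cell experiment. List scores are mean log2 CPM of the tested members less the mean of the first group of the set.

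Genes were chosen by rule, and the text names part of them, picked after their values were seen. Fixed genes were chosen whatever their values, among them ACLY, RB1, cyclin-dependent kinase inhibitors, LMNB1, IL6, CXCL8, IL1B and MKI67. The 5 genes with the largest rise and the 5 with the largest fall were added (3 and 3 for direct contrasts of arrests, siRNAs or drugs and for differences), given an average log2 CPM of at least 3 and groups that do not overlap. Up to 4 members of each list complete them, with an average log2 CPM of at least 1. Some items that the rule would name, and a list built on one of them, are not reported here. Genes with 3 or fewer counts in a group are given as counts summed over its libraries.

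Alternatives were RLE size factors, no low-count filter, DESeq2, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Further alternatives were chosen after the data were seen. The difference between a gene's length and its effective length shows the mean read length of a library, which falls into a longer and a shorter class within both cell sets and kidney; the class was added as a term. In kidney, libraries 1 and 2 are of the longer class (difference 74.32 to 74.34), 3 and 4 of the shorter (74.23 to 74.27). Both pairs were also fitted alone.

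Whether replicate numbers pair libraries was checked from the correlation of their deviations from the group means, which had to exceed 0.1 in each pair. Over genes with a mean log2 CPM of at least 3 this held for Sen against Pro (0.260 to 0.307), Qui against Pro (0.301 to 0.414), Sen against Qui (0.112 to 0.181), siACLY#1 against Sen-Ctrl (0.104 to 0.231) and the kidney drug comparisons (0.157 to 0.535). A first look over all genes did not pair Sen with Qui or siACLY#1 with Sen-Ctrl, so the pairing of these depends on the genes used.

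The tests were tried on simulated counts from real means, with 200 genes changed, fewer than any cell comparison called. Of 67 genes changed 2-fold edgeR recovered 43 for Sen against Pro, 58 for Sen-Ctrl, and 55 and 58 for age in liver and kidney. At 1.5-fold these were 19, 53, 35 and 40 of 67.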

Results

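Messenger RNA was measured in 24 libraries of human IMR-90 fibroblasts, a fetal lung line, and in 32 libraries of mouse liver and kidney. The fibroblasts carried ER:Ras, an oncogenic RAS protein fused to the estrogen receptor, which is switched on by 4-hydroxytamoxifen (4-OHT). In the 8-day experiment the groups were proliferating cells (Pro), cells made quiescent in 0.1% serum for 2 days (Qui), cells made senescent by 8 days of 100 nM 4-OHT (Sen) and senescent cells of a group labelled Sen-siRb/p53, in which RB1 was a target of siRNA. In the 6-day experiment they were proliferating cells (Pro-Ctrl), cells made senescent by 6 days of 4-OHT (Sen-Ctrl), and senescent cells given either of 2 siRNAs against ACLY (Sen-siACLY#1 and Sen-siACLY#2). ACLY encodes ATP citrate lyase, which makes cytosolic acetyl-CoA from citrate. Each cell group had 3 libraries.

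Liver and kidney came from male C57BL/6J mice, either 8 to 9 weeks old with vehicle (Young-veh) or 89 to 90 weeks old with vehicle (Old-veh), dehydrocurvularin (Old-DCV) or JQ1 (Old-JQ1). DCV is an inhibitor of ACLY and was given at 10 mg/kg. JQ1 displaces BET proteins from acetylated histones and was given at 50 mg/kg. Each mouse group had 4 libraries per tissue. The counts over all genes summed to 15974995 to 30339524 per library in the 8-day experiment and 11851295 to 17676871 in the 6-day experiment. They summed to 6511493 to 8356611 in liver and 9717189 to 16624573 in kidney. Below, a value after ± is the standard error of a log2 fold change, or the SD of a TPM value or list score over the 3 (cells) or 4 (mice) libraries of a group. Named genes passed edgeR's test at a 5% false discovery rate unless an adjusted p above it is given, and all libraries of the 2 groups lay apart unless an overlap is stated. A value in brackets after a left-out library or another setting is an adjusted p, and where passing lists are said to run between values, these are their adjusted p over the alternatives. A list called higher or lower passed as a list, and its count gives the members that passed singly. Chance gives such a separation of 3 from 3 libraries with a share of 0.1.

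Senescent cells at 8 days were compared with proliferating cells to describe the senescent transcriptome and the level of ACLY in it. Cytokine and protease genes of the senescence-associated secretory phenotype (SASP) rose, with log2 fold changes of 5.42 ± 0.23 for IL6, 9.78 ± 0.32 for CXCL8, 12.59 ± 0.71 for IL1B and 11.39 ± 1.09 for MMP3 (adjusted p from 1.31e-09 to 3.85e-06). Pro replicate 3 held 19 counts of IL1B against 7 in the other Pro libraries and 5 against 4 of MMP3, and without it IL1B and MMP3 had 14.13 and 12.16. ACLY rose to 345 ± 19.6 TPM against 184 ± 12.7 TPM (log2 fold change 0.97 ± 0.11, adjusted p = 1.77e-05). CDKN2A and CDKN2B, which encode inhibitors of cyclin-dependent kinases, rose (2.27 ± 0.11 and 2.50 ± 0.25). LMNB1, a lamin gene whose loss marks senescence, fell (-1.75 ± 0.41). HRAS rose (0.64 ± 0.17). RB1 had -0.34 ± 0.14, adjusted p = 0.0527.

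Of the SASP factors, 40 of 56 rose and 8 fell, also adjusted over the list alone (adjusted p = 1.57e-16, and adjusted p = 0.106 with an estimated correlation). The RAS-ERK feedback genes, which ERK signalling induces, included DUSP4 and IER3 (9.12 ± 0.30 and 3.93 ± 0.30). In this list 16 of 18 rose, also adjusted over the list alone (adjusted p = 9.66e-12, and adjusted p = 0.106 with an estimated correlation). Extracellular matrix genes moved the other way. Of these genes 2 of 31 rose and 25 fell, also adjusted over the list alone (adjusted p = 3.06e-11, and adjusted p = 0.154 with an estimated correlation), among them DCN and FBLN2 (-5.94 ± 0.24 and -5.22 ± 0.20). The mitotic genes MKI67 and KIF20A fell (-2.51 ± 0.55 and -2.75 ± 0.59). Over the list 1 of 41 rose and 38 fell, also adjusted over the list alone (adjusted p = 0.000256, and adjusted p = 0.634 with an estimated correlation). Sen replicate 2 had a mitosis score of -2.73, against -1.48 and -1.44 in the other Sen libraries. In the response to amino acid shortage and ER stress, PSAT1 and PHGDH of serine synthesis and ASNS fell (-4.38 ± 0.28, -3.98 ± 0.21 and -3.24 ± 0.36). Of the list 2 of 22 rose and 15 fell, also adjusted over the list alone (adjusted p = 2.66e-05, and adjusted p = 0.392 with an estimated correlation).

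Metabolic groups rose. Of the oxidative phosphorylation genes 32 of 39 rose and 1 fell, also adjusted over the list alone. Of the ribosome biogenesis genes 24 of 30 rose, 25 adjusted over the list alone. Of the glycolysis and hypoxia genes 17 of 21 rose and 1 fell, also adjusted over the list alone (these 3 lists had adjusted p = 2.66e-05, 2.66e-05 and 0.000232, and adjusted p = 0.392 for each with an estimated correlation). Examples were the respiratory chain gene COX5A, the ribosome assembly gene BOP1, and CA9 and HK2 (log2 fold changes from 1.02 to 3.17). Cholesterol synthesis, which consumes cytosolic acetyl-CoA, gained NSDHL, FDPS and MSMO1 (1.61 ± 0.13, 1.51 ± 0.14 and 1.42 ± 0.26). In this list 17 of 25 rose and 1 fell, 18 and 1 adjusted over the list alone (adjusted p = 0.00186, and adjusted p = 0.577 with an estimated correlation). The fatty acid and triglyceride list did not pass (adjusted p = 0.0911), although DGAT2 and FASN rose (6.30 ± 0.33 and 1.44 ± 0.17). Other lists that did not pass were acetyl-CoA and citrate supply, DNA replication and E2F targets, interferon-stimulated genes, acetylation enzymes, lysosome, and markers of epithelial, endothelial and immune cells (adjusted p from 0.0667 to 0.884). For the lysosome and epithelial lists the median and the test differed in sign. The endothelial and immune scores were 1.65 ± 0.384 and 2.14 ± 0.172 above Pro (5 higher and 1 lower of 7, and 3 higher of 4).

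Among abundant genes the cystatin gene CST1, which has near-identical paralogs, was also far higher (11.75 ± 0.69), and CORIN far lower (-7.09 ± 0.22). CST1 had 11.02 without Pro replicate 1 and kept 3 Pro counts without Pro replicate 3. Some genes had almost no reads in 1 of the groups, with summed counts in Sen and in Pro of 2151 against 0 for THBD, 5980 against 1 for CCL20, 8594 against 1 for CST4 and 1 against 594 for ADH1B. CDKN1A, which encodes the cell cycle inhibitor p21, rose by less (log2 fold change 0.54 ± 0.20, adjusted p = 0.0326). edgeR called 4207 genes higher and 4303 lower of 14175. CDKN1A lost its call without Pro replicate 1 (0.112), without Pro replicate 2 (0.0578), without Sen replicate 2 (0.0879) and without Sen replicate 3 (0.0707), over all alternatives from 0.00121 to 0.112. The lists that passed ran from 2.89e-25 to 0.634. Of the genes at least 2-fold higher in senescence at 6 days 1256 of 1335 rose here, and of those 2-fold lower 1858 of 2002 fell; lists from this study's own cells are not independent evidence.

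**Figure D1:**
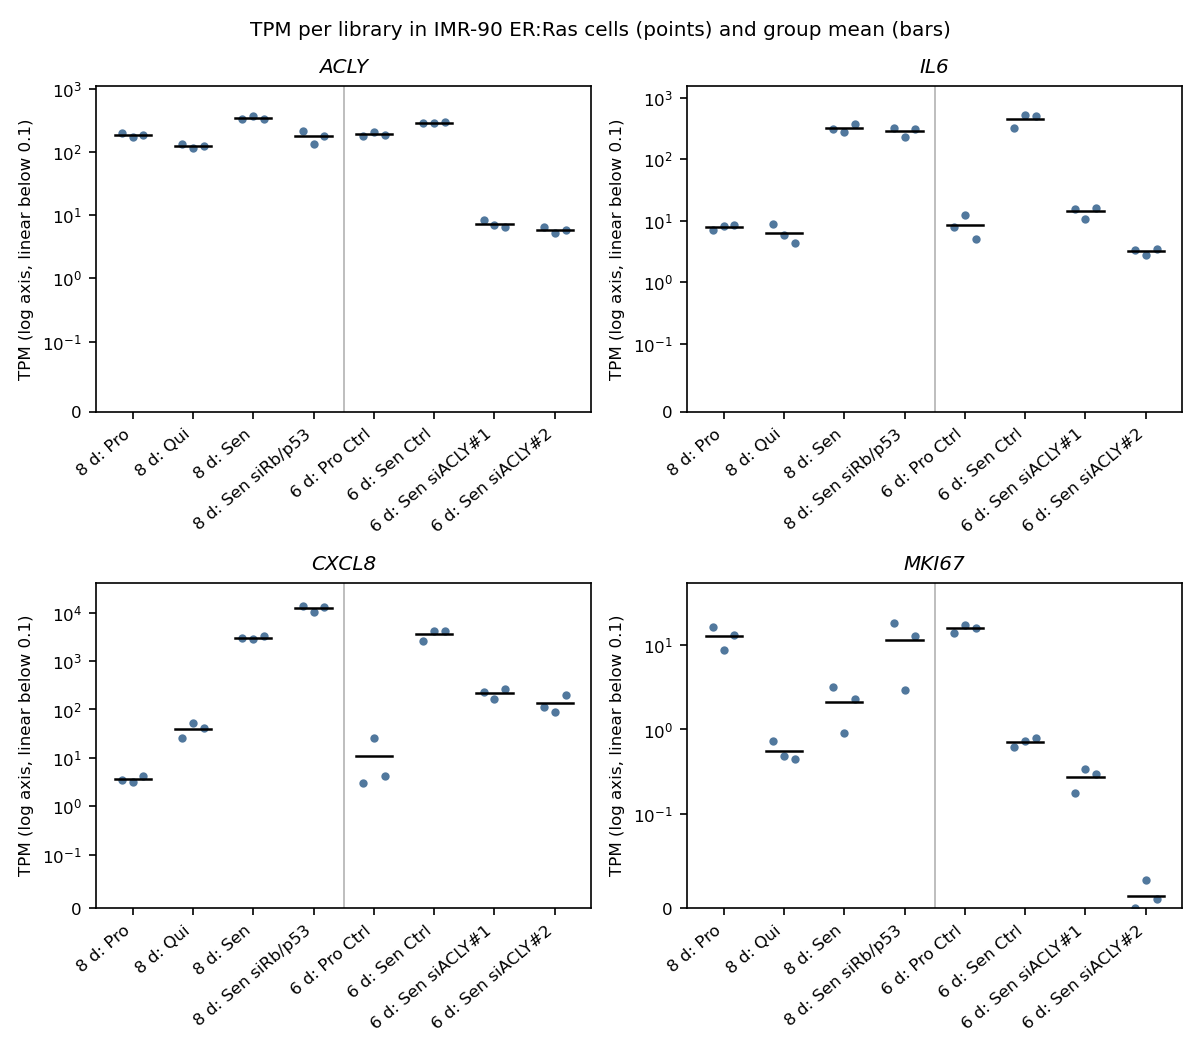
TPM of ACLY, IL6, CXCL8 and MKI67 in each library of the 8 cell groups, on an axis that is linear below 0.1 and logarithmic above it. ACLY lies at 345 ± 19.6 TPM in Sen and 184 ± 12.7 TPM in Pro (SD, n = 3), and at 7.24 ± 0.889 and 5.86 ± 0.545 TPM in the groups given siACLY#1 and siACLY#2.

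Quiescence was compared with proliferation as a form of growth arrest without the oncogene. Cell division genes fell the furthest: -4.59 ± 0.62 for MKI67, -4.72 ± 0.75 for DLGAP5 and -4.70 ± 0.69 for BUB1B (adjusted p from 0.000887 to 0.00182). Of the mitotic genes 41 of 41 fell, also adjusted over the list alone (adjusted p = 1.8e-46, and adjusted p = 0.207 with an estimated correlation). Cholesterol genes fell too: INSIG1 and MVK had -1.53 ± 0.29 and -1.39 ± 0.29. Of these genes 21 of 25 fell, also adjusted over the list alone (adjusted p = 2.98e-14, and adjusted p = 0.304 with an estimated correlation). ACLY fell to 125 ± 8.70 TPM against 184 ± 12.7 TPM (log2 fold change -0.63 ± 0.11, adjusted p = 0.00312).

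Among DNA replication genes TK1 and RRM2 fell (-3.73 ± 0.51 and -3.44 ± 0.43). Over the list 18 of 47 fell, 26 adjusted over the list alone (adjusted p = 2.27e-09, and adjusted p = 0.490 with an estimated correlation). Glycolytic genes fell, PFKP and ENO1 among them (-1.23 ± 0.12 and -0.94 ± 0.20). Of the list 12 of 21 fell, 16 adjusted over the list alone (adjusted p = 2.39e-08, and adjusted p = 0.271 with an estimated correlation). Several SASP factors rose without RAS: CXCL8, IL1B and AREG had 3.41 ± 0.26, 3.49 ± 0.69 and 3.98 ± 0.80. IL6 had -0.39 ± 0.23, adjusted p = 0.274. In this list 27 of 56 rose and 4 fell, 28 and 5 adjusted over the list alone (adjusted p = 3.41e-13, and adjusted p = 0.207 with an estimated correlation). PDK4, which restrains pyruvate oxidation, and NR4A2 rose far (6.84 ± 0.89 and 5.14 ± 0.81), and the contractile genes TAGLN and ACTA2 fell (-2.18 ± 0.31 and -2.06 ± 0.37). Left-out libraries moved some of these folds: IL1B had 5.03 without Pro replicate 3, AREG had 4.70 without Pro replicate 2, and NR4A2 had 4.46 without Qui replicate 3. Interferon-stimulated genes passed (4 higher of 35, 2 adjusted over the list alone; adjusted p = 0.0345, and adjusted p = 0.657 with an estimated correlation), but not with the replicate block (0.0606) or without Pro replicate 2 (0.0744) or Qui replicates 1 (0.219) and 2 (0.394). Extracellular matrix (adjusted p = 0.0533, and 0.0462 with the replicate block), acetyl-CoA supply, RAS-ERK targets and lysosome did not pass (adjusted p from 0.0533 to 0.534).

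edgeR called 1203 genes higher and 1426 lower, and the total of 2629 was 1137 and 1509 without Pro replicates 1 and 3 in turn and 1287 and 1425 without Qui replicates 2 and 3 in turn. With only these 2 groups in the fit it was 4198. Of 69 named genes past the threshold, 27 lost it in at least 1 run without 1 library. Passing lists ran from 1.01e-83 to 0.657 or more.

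Senescence and quiescence, both arrests, were also compared directly. ACLY was higher in Sen (log2 fold change 1.60 ± 0.12, adjusted p = 2.66e-07), as was the SASP gene IL6 (5.81 ± 0.23). Summed counts in Sen and in Qui were 3426 against 0 for WNT7B and 1 against 5484 for ADH1B. The cholesterol gene MSMO1 was higher (2.73 ± 0.28), as was FASN, the fatty acid synthase (2.24 ± 0.17). DCN and PDK4 were lower (-6.27 ± 0.24 and -7.86 ± 0.97). MKI67 was higher in Sen than in Qui (2.08 ± 0.60).

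The lists of cholesterol synthesis (22 higher of 25, also adjusted over the list alone), SASP factors (35 higher and 10 lower of 56, 35 and 11 adjusted over the list alone) and mitosis (24 higher of 41, 22 adjusted over the list alone) were higher in Sen (adjusted p = 2.99e-08, 5.62e-08 and 0.00722, and adjusted p from 0.261 to 0.693 with an estimated correlation). Extracellular matrix (2 higher and 19 lower of 31, also adjusted over the list alone) and interferon-stimulated genes (2 higher and 21 lower of 35, 3 and 22 adjusted over the list alone) were lower (adjusted p = 3.21e-07 and 0.0107, and adjusted p from 0.261 to 0.660 with an estimated correlation). E2F targets, acetyl-CoA supply and lysosome did not pass (adjusted p from 0.116 to 0.986). CDKN1A had 0.46 ± 0.20, adjusted p = 0.0568, or 0.0210 with the replicate block. edgeR called 4580 genes higher and 4732 lower. The passing lists ran from 2.05e-11 to 0.693.

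Sen-siRb/p53 cells were compared with Sen cells to see which changes of senescence depend on the siRNA targets, of which RB1 restrains entry into S phase. RB1, the target reported here, fell in Sen-siRb/p53 to 3.38 ± 0.527 TPM against 33.1 ± 1.98 TPM (log2 fold change -3.18 ± 0.16, adjusted p = 1.96e-07). ACLY fell to 177 ± 41.5 TPM against 345 ± 19.6 TPM (log2 fold change -0.86 ± 0.11, adjusted p = 5.73e-05). Division genes rose, with 2.49 ± 0.55 for MKI67, 3.77 ± 0.54 for CDK1 and 3.39 ± 0.43 for TOP2A (adjusted p from 4.5e-05 to 0.00208). The replication genes MCM6 and CHAF1B and LMNB1 rose too (3.04 ± 0.18, 2.81 ± 0.34 and 2.12 ± 0.41). CDKN1A fell (-0.80 ± 0.20), while CDKN2A and CDKN2B rose (1.02 ± 0.10 and 1.87 ± 0.24).

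Of the mitotic genes 40 of 41 rose, also adjusted over the list alone. Of the replication and E2F genes 38 of 47 rose and 1 fell, also adjusted over the list alone (for both lists adjusted p = 7.05e-08 and 1.3e-07, and adjusted p = 0.544 for each with an estimated correlation). Sen-siRb/p53 replicate 2 had scores of -0.745 and -0.0225 on these lists, against 0.762 to 1.25 and 0.740 to 1.36 in the other libraries of the group, and without it they had adjusted p = 1.06e-17 and 1.45e-14. Endothelial markers did not pass (2 higher and 2 lower of 7; adjusted p = 0.713), with a score of 2.50 ± 0.476 against 1.65 ± 0.384 in Sen. SASP factors split: CXCL8, IL24 and AREG rose (2.14 ± 0.22, 5.95 ± 1.02 and 3.85 ± 0.71). IL1B fell (-1.58 ± 0.41), and IL6 had -0.05 ± 0.18, adjusted p = 0.811. Of these genes 25 of 56 rose and 9 fell, 25 and 10 adjusted over the list alone (adjusted p = 0.0242, and adjusted p = 0.544 with an estimated correlation). The ER stress and amino acid response rose with GDF15, DDIT3, PHGDH and ASNS (5.08 ± 0.79, 4.55 ± 0.52, 4.13 ± 0.21 and 3.93 ± 0.37). Without Sen-siRb/p53 replicate 2 the log2 fold changes of IL24, AREG, GDF15 and DDIT3 were 4.19, 2.96, 3.52 and 3.74, and without Sen replicate 2 AREG had 4.45. Over the list 15 of 22 rose and 1 fell, 15 and 2 adjusted over the list alone (adjusted p = 9.11e-11, and adjusted p = 0.257 with an estimated correlation). Of the matrix genes 20 of 31 rose and 1 fell, also adjusted over the list alone (adjusted p = 1.93e-05, and adjusted p = 0.472 with an estimated correlation).

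Ribosome biogenesis (1 higher and 23 lower of 30, also adjusted over the list alone) and glycolysis (2 higher and 16 lower of 21, also adjusted over the list alone) fell, with LDHA at -1.78 ± 0.27, and interferon-stimulated genes (16 higher of 35, 15 adjusted over the list alone) rose (adjusted p = 7.81e-05, 0.00413 and 0.00581, and adjusted p from 0.544 to 0.599 with an estimated correlation). DGAT2 fell (-4.26 ± 0.28), but the lists of cholesterol synthesis, fatty acid synthesis and acetyl-CoA supply did not pass (adjusted p from 0.158 to 0.274). Of the genes higher in senescence at 6 days 307 of 1335 rose and 620 fell, and of those lower 1004 of 2002 rose and 187 fell, again not independent evidence (adjusted p = 0.0419 for each with an estimated correlation). edgeR called 4213 genes higher and 4055 lower. IL1B lost its call by DESeq2 (0.0865), over all alternatives from 0.000601 to 0.0865. The SASP factors list lost its call without Sen-siRb/p53 replicate 2 (0.0878), and passing lists ran from 1.06e-17 to 0.599.

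Senescent and proliferating cells were compared again at 6 days, as the controls of the ACLY knockdown. SASP genes rose: 5.73 ± 0.30 for IL6, 8.35 ± 0.72 for CXCL8, 8.93 ± 0.83 for IL1B, 9.01 ± 0.76 for CCL20 and 8.81 ± 0.65 for CXCL5 (adjusted p from 1.5e-07 to 1.06e-05). Replicate 2 held most Pro-Ctrl counts of some of them, with 280 counts of IL1B against 5 in the other Pro-Ctrl libraries, 316 against 71 of CXCL8, 133 against 8 of CXCL5 and 7 against 0 of CCL20. Without it the log2 fold changes of IL1B, CXCL5 and CXCL8 were 13.97, 12.21 and 10.07, and without Pro-Ctrl replicate 1 those of IL1B and CCL20 were 8.33 and 8.41. ACLY rose to 291 ± 4.39 TPM against 191 ± 17.2 TPM (log2 fold change 0.66 ± 0.07, adjusted p = 3.5e-08). Division genes fell, with -4.39 ± 0.14 for MKI67, -4.64 ± 0.17 for KIF20A and -4.25 ± 0.11 for TK1, as did LMNB1 (-2.88 ± 0.12). CDKN1A, CDKN2A and CDKN2B rose (0.84 ± 0.05, 1.80 ± 0.08 and 3.14 ± 0.09). The matrix gene DCN fell (-5.58 ± 0.11), and DUSP4, which dephosphorylates MAP kinases, rose (7.24 ± 0.26). Without Pro-Ctrl replicate 2 DUSP4 had 7.92.

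Of the mitotic genes 41 of 41 fell, also adjusted over the list alone. Of the extracellular matrix genes 5 of 31 rose and 24 fell, also adjusted over the list alone. Of the RAS-ERK genes 18 of 18 rose, also adjusted over the list alone (in this order adjusted p = 3.48e-39, 1.48e-17 and 3.47e-17). These calls held: adjusted p from 0.00314 to 0.0303 with an estimated correlation. Among SASP factors 43 of 55 rose and 8 fell, also adjusted over the list alone (adjusted p = 2.48e-09, and adjusted p = 0.320 with an estimated correlation). Among replication and E2F genes 2 of 48 rose and 43 fell, also adjusted over the list alone (adjusted p = 9.84e-08, and adjusted p = 0.0836 with an estimated correlation). Oxidative phosphorylation (32 higher and 2 lower of 39, also adjusted over the list alone), ribosome biogenesis (26 higher and 1 lower of 30, also adjusted over the list alone), glycolysis (18 higher and 2 lower of 21, also adjusted over the list alone) and cholesterol synthesis (18 higher and 3 lower of 25, also adjusted over the list alone) rose (adjusted p = 0.00263, 9.89e-05, 0.000539 and 0.0314, and adjusted p from 0.528 to 0.655 with an estimated correlation), with CA9, DGAT2 and NSDHL at 3.29 ± 0.39, 5.64 ± 0.25 and 1.26 ± 0.08. PHGDH fell (-2.82 ± 0.47). Without Sen-Ctrl replicate 2 PHGDH had -3.69, and Pro-Ctrl replicate 2 held 7 counts of DGAT2, against 3 in the other Pro-Ctrl libraries. The ER stress and amino acid list, interferon-stimulated genes, fatty acid synthesis, acetyl-CoA supply, acetylation enzymes and lysosome did not pass (adjusted p from 0.150 to 0.960). The median and the test differed in sign for lysosome. Endothelial and immune marker scores were 1.47 ± 0.306 and 2.38 ± 0.208 above Pro-Ctrl (5 higher and 1 lower of 7, and 3 higher of 3; adjusted p from 0.142 to 0.293), and did not pass.

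Summed counts in Sen-Ctrl and in Pro-Ctrl were 977 against 0 for CST2 and 3 against 1679 for TOX. edgeR called 4921 genes higher and 4974 lower of 13515. The cholesterol synthesis and uptake list lost its call without Sen-Ctrl replicate 1 (0.0603), and passing lists ran from 1.76e-16 to 0.655.

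ACLY was depleted in senescent cells with 2 siRNAs, each compared with Sen-Ctrl, to find which senescence genes depend on it. With siACLY#1, ACLY fell to 7.24 ± 0.889 TPM against 291 ± 4.39 TPM (log2 fold change -5.36 ± 0.09, adjusted p = 1.13e-18). SASP genes fell with it: -5.06 ± 0.28 for IL6, -4.12 ± 0.56 for CXCL8, -4.59 ± 0.63 for IL1B, -6.61 ± 0.55 for CXCL5 and -5.06 ± 0.30 for MMP3 (adjusted p from 5.68e-07 to 0.000279). Of the SASP factors 12 of 55 rose and 36 fell, 12 and 38 adjusted over the list alone (adjusted p = 0.000180, and adjusted p = 0.912 with an estimated correlation). CDKN2A and CDKN1A rose, and MKI67 fell (1.15 ± 0.07, 0.39 ± 0.05 and -1.46 ± 0.24). Epithelial markers did not pass (2 higher of 4; adjusted p = 0.435), with a score of 0.627 ± 0.0370 against -0.409 ± 0.238 in Sen-Ctrl (-0.661 ± 0.275 with siACLY#2).

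The matrix gene FBLN2 rose and BGN fell (3.29 ± 0.18 and -1.94 ± 0.15). Of these genes 18 of 31 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.912 with an estimated correlation). Among RAS-ERK genes EGR1 and IER3 fell (-1.97 ± 0.23 and -1.93 ± 0.15). Over the list 3 of 18 rose and 10 fell, 4 and 10 adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.912 with an estimated correlation). The lipid genes DGAT2 and SCD rose (1.86 ± 0.10 and 1.11 ± 0.09), but fatty acid synthesis, cholesterol synthesis, acetyl-CoA supply, mitosis and interferon-stimulated genes did not pass (adjusted p from 0.184 to 0.967). With the replicate block, ribosome biogenesis and glycolysis passed (adjusted p = 0.0493 for each, against 0.0563 and 0.129 without it).

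ADAMTSL1, ANKRD1 and SORL1 rose the furthest of abundant genes, and SERPINA9 and SLC7A2 fell far (4.53 ± 0.16, 4.18 ± 0.22, 3.72 ± 0.21, -6.82 ± 0.31 and -5.42 ± 0.28). Of the genes 2-fold higher in senescence at 8 days, 803 of 1503 fell and 270 rose, and of those 2-fold lower 931 of 2051 rose and 224 fell (adjusted p = 0.0219 and 0.0121 with an estimated correlation), not independent evidence. edgeR called 3681 genes higher and 3863 lower. Lists that passed ran from 1.93e-06 to 0.912.

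With siACLY#2, ACLY fell to 5.86 ± 0.545 TPM against 291 ± 4.39 TPM (log2 fold change -5.60 ± 0.09, adjusted p = 7.59e-19). IL6 fell to 3.19 ± 0.361 TPM against 450.5 ± 112 TPM, and log2 fold changes of SASP genes were -7.11 ± 0.35 for IL6, -4.74 ± 0.58 for CXCL8, -7.67 ± 0.60 for CXCL5, -5.57 ± 0.36 for CSF2 and -2.44 ± 0.57 for IL1B (adjusted p from 1.66e-07 to 0.00501). Of the SASP factors 11 of 55 rose and 35 fell, 12 and 35 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.933 with an estimated correlation). Endothelial markers did not pass (0 higher and 4 lower of 7; adjusted p = 0.0520), with a score of 0.0355 ± 0.159 against 1.47 ± 0.306 (0.859 ± 0.205 with siACLY#1). Division genes fell below Sen-Ctrl, with summed counts of 3 against 174 for MKI67, 1 against 45 for CDK1 and 1 against 32 for NDC80. Of the list 39 of 41 fell, 40 adjusted over the list alone (adjusted p = 3.21e-07, and adjusted p = 0.0730 with an estimated correlation). RB1 and LMNB1 fell, and CDKN2B and CDKN1A rose (-1.27 ± 0.07, -1.11 ± 0.18, 2.16 ± 0.08 and 0.73 ± 0.05).

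Ribosome assembly genes rose, BOP1 among them (1.04 ± 0.07). Of these genes 26 of 30 rose and 2 fell, 27 and 2 adjusted over the list alone (adjusted p = 5.26e-06, and adjusted p = 0.693 with an estimated correlation). In the glycolysis and hypoxia list CA9 and ALDOC fell (-3.65 ± 0.42 and -2.18 ± 0.26). Over the list 2 of 21 rose and 16 fell, also adjusted over the list alone (adjusted p = 0.000126, and adjusted p = 0.709 with an estimated correlation). Of the acetylation enzymes and readers 14 of 24 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.00473, and adjusted p = 0.0730 with an estimated correlation). Cholesterol synthesis, fatty acid synthesis, acetyl-CoA supply and interferon-stimulated genes did not pass (adjusted p from 0.0552 to 0.992).

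FAM84A, ADAMTSL1 and SLIT2 rose the furthest of the abundant genes, and SERPINA9 and C15orf48 fell far (5.25 ± 0.12, 4.02 ± 0.17, 3.84 ± 0.17, -7.24 ± 0.32 and -6.44 ± 0.26). The list of genes higher at 8 days, not independent evidence here, had 389 rises and 714 falls (adjusted p = 0.00168, and adjusted p = 0.295 with an estimated correlation), and the list of genes lower at 8 days had 606 and 589 (adjusted p = 0.196). edgeR called 4353 genes higher and 4355 lower. IL1B lost its call by DESeq2 (0.0959), over all alternatives from 0.000760 to 0.0959. The passing lists ran from 2.3e-13 to 0.933.

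**Figure D2:**
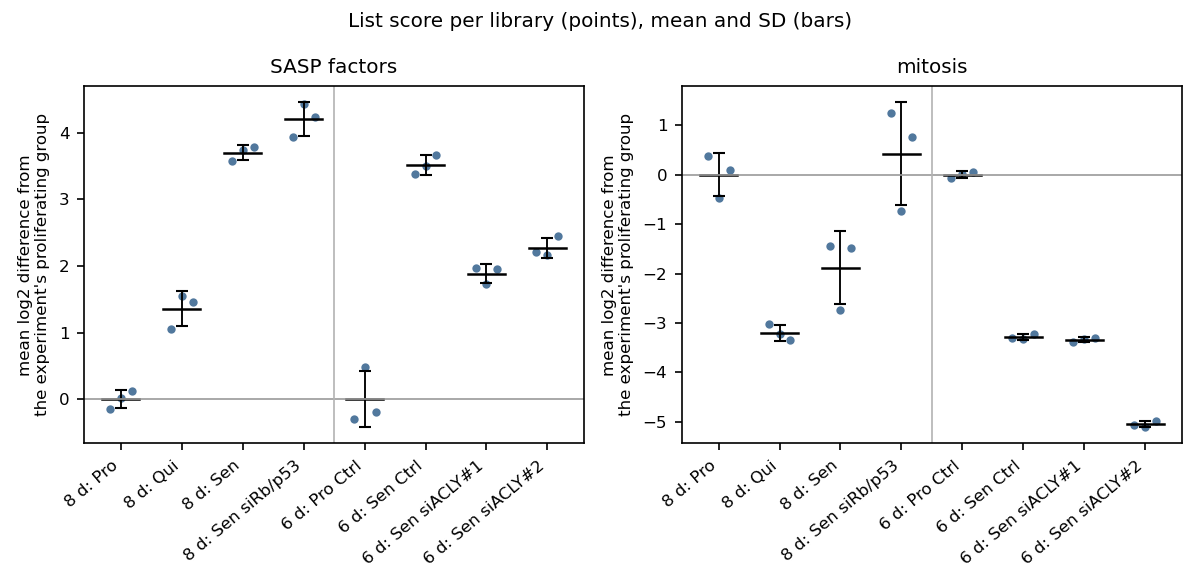
Scores of the SASP factor and mitosis lists in each library of the 8 cell groups, with the mean and SD of each group (n = 3). A score is the mean log2 CPM of the tested members of a list minus its mean over the proliferating libraries of the same experiment.

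The 2 ACLY siRNAs were compared with each other because both lowered the same target. ACLY stood at 7.24 ± 0.889 TPM against 5.86 ± 0.545 TPM (log2 fold change 0.25 ± 0.10, adjusted p = 0.0383), with the libraries of the 2 groups overlapping. IL6 was higher with siACLY#1, IL1B and MMP3 lower (2.05 ± 0.54, -2.16 ± 0.58 and -4.80 ± 0.30), and CXCL8 had 0.63 ± 0.52, adjusted p = 0.310. Division genes were higher with siACLY#1, with summed counts of 62 against 3 for MKI67 and 41 against 1 for CDK1, as was ANKRD1, a target of YAP signalling (7.18 ± 0.32). PTGS2, the prostaglandin synthase COX-2, and GDF15 were lower (-5.09 ± 0.35 and -2.94 ± 0.16). Mitosis (38 higher of 41, also adjusted over the list alone), glycolysis (18 higher and 1 lower of 21, also adjusted over the list alone) and interferon-stimulated genes (24 higher and 3 lower of 32, 25 and 4 adjusted over the list alone) were higher with siACLY#1 and ribosome biogenesis lower (28 lower of 30, also adjusted over the list alone; adjusted p = 1.32e-05, 3.88e-06, 0.0390 and 5.58e-08, and adjusted p from 0.273 to 0.802 with an estimated correlation). edgeR called 9469 genes, 4710 higher and 4759 lower. ACLY lost its call without Sen-siACLY#1 replicate 1 (0.157), without Sen-siACLY#1 replicate 2 (0.0547), without Sen-siACLY#2 replicate 2 (0.161), without Sen-siACLY#2 replicate 3 (0.0674), with the replicate block (0.0605) and with the read-length class as a term (0.0743) and IL1B by DESeq2 (0.141), over all alternatives from 0.00226 to 0.161. The interferon-stimulated genes list lost its call without Sen-siACLY#1 replicate 1 (0.0676) and without Sen-siACLY#1 replicate 2 (0.0578), and passing lists ran from 3.95e-12 to 0.802.

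Across genes the fold changes of the 2 siRNAs against Sen-Ctrl had r = 0.239 and a covariance of 0.182, where unchanged groups simulated against the same 3 controls gave r = 0.517 and a covariance of 0.0253 ± 0.00412 (SD, 20 draws); genes are not independent replicates. Among genes called for both, 1479 were higher with both, 1572 lower with both and 2207 opposite, where independent lists would share 1186, 1245 and 2430. With 3 controls a split into parts of 2 libraries was not possible, so part of the excess may come from the shared controls.

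**Figure D3:**
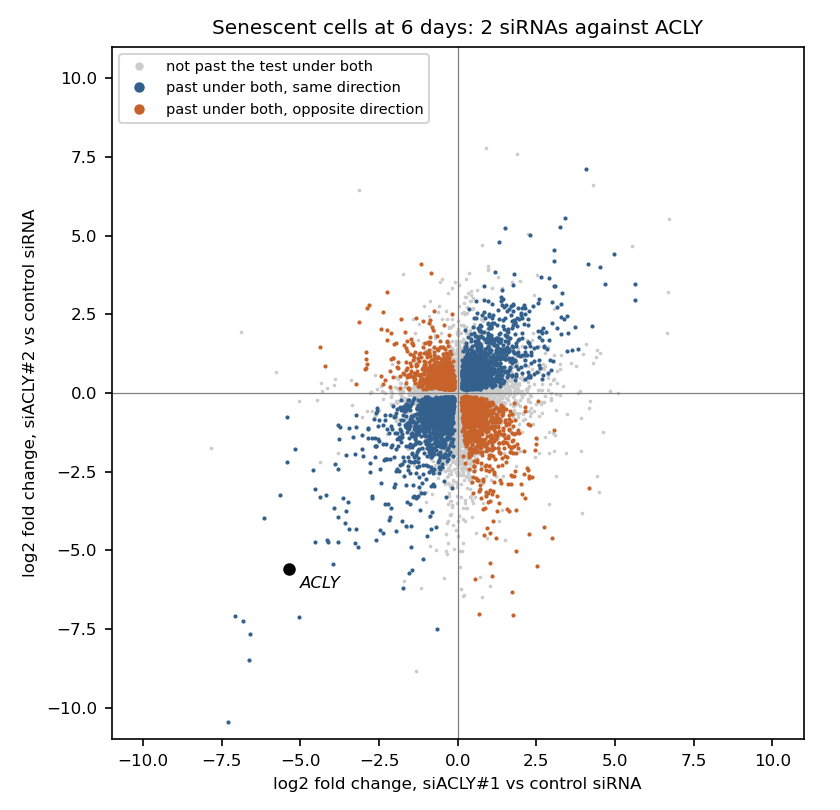
Log2 fold change of each tested gene with siACLY#1 (horizontal axis) and siACLY#2 (vertical axis), both against Sen-Ctrl (n = 3 per group). Of the genes called for both siRNAs, 1479 lie in the upper right, 1572 in the lower left and 2207 in the remaining quadrants.

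The senescence effect at 6 days was set against that at 8 days, although time and experiment cannot be told apart in this design. As lists, the effect was more negative at 6 days for mitotic genes (2 lower of 41, 37 adjusted over the list alone) and for replication and E2F genes (0 lower of 48, 37 adjusted over the list alone; adjusted p = 1.14e-35 and 9.37e-27, and adjusted p from 0.133 to 0.172 with an estimated correlation). The mitosis score was -3.32 to -3.22 in Sen-Ctrl, -2.73 in Sen replicate 2 and -1.48 and -1.44 in the other Sen libraries, and without Sen replicate 2 the list had adjusted p = 2.17e-66. Single genes past the threshold included HTRA1, with a more positive effect at 6 days, and MYBL1, RACGAP1 and ECT2, with a more negative one (0.76 ± 0.14, -1.66 ± 0.30, -1.20 ± 0.18 and -0.71 ± 0.12). For ACLY the difference was -0.29 ± 0.10, adjusted p = 0.176. edgeR called 35 genes (11 higher and 24 lower), and this count was 441 with DESeq2, 474 with the replicate block, 98 without the low-count filter, 384, 7 and 7 without Pro replicates 1, 2 and 3 in turn, 102, 785 and 1 without Sen replicates 1, 2 and 3 in turn, 3, 1 and 2 without Pro-Ctrl replicates 1, 2 and 3 in turn and 124, 1 and 1 without Sen-Ctrl replicates 1, 2 and 3 in turn. All 10 named genes past the threshold lost it in at least 1 such run. Passing lists ran from 2.17e-66 to 0.930 or more.

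In liver, old and young mice on vehicle were compared to see what age changed. Old livers had more of Serpine2, the joining chain gene Jchain of plasma cells, and Atp11a (2.23 ± 0.17, 2.53 ± 0.44 and 1.72 ± 0.12; adjusted p from 1.89e-07 to 0.00782). Tceal8 and the methyltransferase gene Inmt fell (-1.66 ± 0.19 and -1.19 ± 0.20). H2-D1, a class I antigen gene, rose (0.71 ± 0.13), as did Srebf2, the regulator of cholesterol synthesis (0.44 ± 0.08). Acly stood at 146 ± 40.1 TPM against 110.0 ± 24.3 TPM and Cdkn1a at 6.59 ± 4.02 TPM against 3.87 ± 1.67 TPM (log2 fold changes 0.34 ± 0.28, adjusted p = 0.708, and 0.70 ± 0.47, adjusted p = 0.623). Acly lies at 100476353 to 100528000 on the minus strand of chromosome 11 and Cdkn1a at 29090976 to 29100727 on the plus strand of chromosome 17 (mm10, GENCODE M21).

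Antigen presentation genes were higher as a list (7 higher of 20, 18 adjusted over the list alone), as were interferon-stimulated genes (2 higher of 34, 13 adjusted over the list alone) and cholesterol synthesis (1 higher of 25, 2 adjusted over the list alone) (adjusted p = 8.74e-22, 4.57e-13 and 6.41e-15, and adjusted p from 0.417 to 0.561 with an estimated correlation). Oxidative phosphorylation (1 lower of 38, 7 adjusted over the list alone) and PPAR-alpha targets (0 lower of 29, 10 adjusted over the list alone) were lower as lists (adjusted p = 7.56e-10 and 6.35e-08, and adjusted p from 0.561 to 0.604 with an estimated correlation). B cell and plasma cell markers (1 higher of 3, also adjusted over the list alone) passed as well (adjusted p = 0.0290, and adjusted p = 0.561 with an estimated correlation), and macrophage markers did not (adjusted p = 0.0628).

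edgeR called 120 genes higher and 39 lower of 12092, and DESeq2 289. The count was 85 and 96 without Young-veh replicates 1 and 4 in turn and 74 and 85 without Old-veh replicates 3 and 4 in turn, and 14 of 27 named genes lost their call in such a run. The B lymphocyte and plasma cell list lost its call without Young-veh replicate 4 (0.0992) and without Old-veh replicate 2 (0.0803), and passing lists ran from 2.45e-30 to 0.604.

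DCV was compared with vehicle in old liver to see what ACLY inhibition changed. No gene passed with edgeR, and DESeq2 called 5. With edgeR 652 of 12092 genes had an unadjusted p under 0.05, near the 5% that chance alone gives. Acly stood at 185 ± 43.6 TPM against 146 ± 40.1 TPM (log2 fold change 0.40 ± 0.28, adjusted p = 0.960). Interferon-stimulated genes were lower as a list (0 lower of 34, 21 adjusted over the list alone), as was antigen presentation (0 lower of 20, 2 adjusted over the list alone; adjusted p = 2.86e-25 and 6.92e-09, and adjusted p from 0.384 to 0.465 with an estimated correlation). Fatty acid synthesis (0 of 26 past the threshold, also adjusted over the list alone) and cytochrome P450 genes (0 of 34 past the threshold, also adjusted over the list alone) were higher as lists (adjusted p = 9.34e-08 and 9.34e-08, and adjusted p = 0.384 for each with an estimated correlation). Macrophage markers were lower as a list too (0 of 20 past the threshold, also adjusted over the list alone; adjusted p = 0.000872, and adjusted p = 0.494 with an estimated correlation). The macrophage list lost its call without Old-veh replicate 4 (0.153). Over the alternatives the passing lists had adjusted p from 8.71e-46 to 0.504, and the number of single genes was 1 without Old-DCV replicate 4.

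JQ1 was compared with vehicle in old liver as an inhibitor of BET proteins, which read histone acetylation. The histone gene Hist2h2aa1 rose and the growth arrest-specific gene Gas7 fell (2.24 ± 0.20 and -1.65 ± 0.16; adjusted p from 1.87e-05 to 3.46e-05); histone genes have near-identical copies and transcripts mostly without a poly(A) tail. Angptl4, a PPAR target that inhibits lipoprotein lipase, rose (0.72 ± 0.12). Hexim1, a gene that BET inhibition is known to induce, had -0.15 ± 0.10, adjusted p = 0.587. PPAR-alpha targets were higher as a list (2 higher of 29, 7 adjusted over the list alone), as was fatty acid synthesis (1 higher and 0 lower of 26, 8 and 3 adjusted over the list alone; adjusted p = 4.68e-11 and 6.66e-05, and adjusted p = 0.520 for each with an estimated correlation). Antigen presentation (1 lower of 20, 3 adjusted over the list alone) and interferon-stimulated genes (0 of 34 past the threshold, also adjusted over the list alone) were lower as lists (adjusted p = 6.65e-09 and 2.1e-08, and adjusted p = 0.520 for each with an estimated correlation). Macrophage markers were lower as a list (0 of 20 past the threshold, also adjusted over the list alone; adjusted p = 0.00213, and adjusted p = 0.609 with an estimated correlation).

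edgeR called 43 genes higher and 22 lower, DESeq2 240, and edgeR with only these 2 groups in the fit 27. The count was 40, 16, 15 and 17 without Old-veh replicates 1, 2, 3 and 4 in turn and 10 and 4 without Old-JQ1 replicates 2 and 3 in turn. Of 18 named genes, 16 lost their call in such a run. Angptl4 lost its call without Old-JQ1 replicate 3 (0.0778), over all alternatives from 1.99e-05 to 0.0778. The macrophage list lost its call without Old-veh replicate 4 (0.109) and without Old-JQ1 replicate 4 (0.173), and passing lists ran from 2.3e-17 to 0.609.

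The 2 drugs, at different doses, were also set against each other in liver. The sulfotransferase gene Sult5a1 and the transporter gene Slc13a3 were higher with DCV, and Hist2h2aa1 and Angptl4 were lower (1.91 ± 0.30, 0.87 ± 0.13, -1.77 ± 0.19 and -1.04 ± 0.12; adjusted p from 0.000148 to 0.00884). PPAR-alpha targets were lower with DCV (4 lower of 29, 11 adjusted over the list alone) and cytochrome P450 genes higher (6 higher and 0 lower of 34, 11 and 1 adjusted over the list alone; adjusted p = 1.02e-13 and 1.49e-08, and adjusted p = 0.440 for each with an estimated correlation). Interferon-stimulated genes did not pass (adjusted p = 0.153). edgeR called 94 genes, 63 higher and 31 lower, DESeq2 267, and edgeR with only these 2 groups 56. The count was 36 and 36 without Old-DCV replicates 2 and 4 in turn and 33, 20 and 294 without Old-JQ1 replicates 2, 3 and 4 in turn. Passing lists ran from 4.33e-15 to 0.440.

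Old and young kidneys on vehicle were compared in the same way. Cdkn1a rose to 15.7 ± 1.87 TPM against 6.15 ± 0.384 TPM (log2 fold change 1.20 ± 0.14, adjusted p = 4.85e-05), as did Eda2r and Phlda3 (2.80 ± 0.36 and 1.21 ± 0.15). Genes of tubular injury rose: Havcr1, which encodes kidney injury molecule KIM-1, Lcn2 and Cd44 (2.19 ± 0.42, 1.97 ± 0.43 and 1.16 ± 0.24). Immune genes rose: Jchain of plasma cells, the complement gene C4b, the macrophage gene Adgre1, the interferon-stimulated Oasl1, and H2-Ab1 and Cd74 of antigen presentation (4.98 ± 0.82, 2.64 ± 0.25, 1.31 ± 0.20, 1.34 ± 0.23, 1.11 ± 0.22 and 1.06 ± 0.21). Without Old-veh replicate 1 Jchain had 4.37. Aldh1a1 and Cyp2d12 rose as well, and Mogat2 and Ttr fell (2.90 ± 0.18, 2.87 ± 0.12, -2.06 ± 0.23 and -1.33 ± 0.19). Adjusted p values of these genes ran from 4.02e-11 to 0.00879. Acly stood at 114 ± 8.51 TPM against 88.9 ± 11.0 TPM (log2 fold change 0.22 ± 0.08, adjusted p = 0.0808).

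Of the interferon-stimulated genes 14 of 34 rose, 27 adjusted over the list alone. Of the antigen presentation genes 15 of 21 rose, 17 adjusted over the list alone. Of the macrophage markers 11 of 16 rose, 14 adjusted over the list alone. Of the acute phase and complement genes 10 of 19 rose, 14 adjusted over the list alone (the 4 lists had adjusted p = 1.36e-14, 5.49e-14, 1.6e-13 and 1.11e-13, and adjusted p from 0.00528 to 0.149 with an estimated correlation). Of the SASP factors 10 of 41 rose, 19 adjusted over the list alone (adjusted p = 3.43e-10, and adjusted p = 0.0259 with an estimated correlation). Among tubular injury genes 7 of 19 rose and 0 fell, 10 and 1 adjusted over the list alone (adjusted p = 1.04e-05, and adjusted p = 0.220 with an estimated correlation). The calls for SASP factors and acute phase genes held that way. Fibroblast markers (4 higher and 0 lower of 13, 5 and 1 adjusted over the list alone) and extracellular matrix genes such as Lum and Thbs2 (1.62 ± 0.29 and 1.08 ± 0.14; 5 higher and 1 lower of 31, 8 and 2 adjusted over the list alone) were higher as lists, as were T and NK (2 higher of 11, 9 adjusted over the list alone) and B cell markers (3 higher of 9, also adjusted over the list alone), with adjusted p = 0.000745, 0.00329, 1.58e-05 and 0.000745, and adjusted p from 0.105 to 0.512 with an estimated correlation. Oxidative phosphorylation (4 lower of 38, 32 adjusted over the list alone), collecting duct markers such as Atp6v1g3 (-0.61 ± 0.12; 5 lower of 12, 7 adjusted over the list alone) and PPAR-alpha targets such as Acadm (-0.48 ± 0.08; 2 lower of 29, 5 adjusted over the list alone) were lower as lists (adjusted p = 1.78e-12, 1.17e-05 and 0.00236, and adjusted p from 0.110 to 0.491 with an estimated correlation). Mitosis did not pass (adjusted p = 0.362).

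edgeR called 664 genes higher and 359 lower of 14288, and 29 of 79 named genes lost their call without 1 library. Young-veh replicate 1 stood apart, at -37.0 on the first principal component (33.5% of the variance) against -10.2 to -5.41 in the rest of its group, and the 10 largest genes took 9.27% of its counts against 7.90 to 8.16%. The count was 580 without Young-veh replicate 1 and 544 without Old-veh replicate 2. Within kidney libraries 1 and 2 it was 22 and within 3 and 4, with slightly shorter reads, 317, or 1576 with the read-length class as a term. With only these 2 groups it was 572. The lists that passed ran from 1.11e-27 to 0.512.

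DCV was compared with vehicle in old kidney. No gene passed with edgeR, with 510 genes at an unadjusted p under 0.05; DESeq2 called 2. Interferon-stimulated genes were lower as a list (0 lower of 34, 19 adjusted over the list alone; adjusted p = 8.44e-38, and adjusted p = 0.0549 with an estimated correlation), as was antigen presentation (0 lower of 21, 3 adjusted over the list alone; adjusted p = 6.04e-18, and adjusted p = 0.203 with an estimated correlation). Macrophage markers did not pass (adjusted p = 0.789; their median and test differed in sign; 0.00563, higher, without Old-veh replicate 4), nor did SASP factors (adjusted p = 0.629). Collecting duct markers (0 of 12 past the threshold, also adjusted over the list alone) and tubular injury genes (0 of 19 past the threshold, also adjusted over the list alone) were higher as lists (adjusted p = 0.000177 and 0.000762, and adjusted p from 0.218 to 0.366 with an estimated correlation). Acly stood at 118 ± 6.67 TPM against 114 ± 8.51 TPM (log2 fold change 0.05 ± 0.08, adjusted p = 1.000). The number of single genes was 5 without Old-veh replicate 1, and 0 within libraries 1 and 2 and 7 within libraries 3 and 4. The ER stress genes were higher as a list (0 of 21 past the threshold, also adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.402 with an estimated correlation). It lost its call with the replicate block (0.0561), without the low-count filter (0.0515), and without Old-veh replicate 1 (0.293) or Old-DCV replicates 2 (0.112) and 3 (0.351). Lists that passed ran from 4.72e-82 to 0.494.

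JQ1 was compared with vehicle in old kidney. Complement gene C4b, Car3, the growth factor gene Mdk and Bhmt of methionine metabolism fell (-1.54 ± 0.23, -1.40 ± 0.20, -1.22 ± 0.13 and -1.51 ± 0.22; adjusted p from 5.62e-05 to 0.00297). Hist2h2aa1, Ces1g and Pck1, a gene of glucose synthesis, rose (1.36 ± 0.12, 0.98 ± 0.12 and 0.94 ± 0.11; adjusted p from 1.21e-05 to 0.000442). The macrophage gene Mpeg1 and the matrix gene Thbs2 fell (-0.88 ± 0.15 and -0.76 ± 0.14). The clock gene Usp2 rose (0.69 ± 0.13).

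Mitosis (2 lower of 38, 28 adjusted over the list alone), antigen presentation (2 lower of 21, 17 adjusted over the list alone), interferon-stimulated genes (2 lower of 34, 18 adjusted over the list alone), macrophage markers (0 higher and 4 lower of 16, 1 and 7 adjusted over the list alone) and extracellular matrix (1 lower of 31, 3 adjusted over the list alone) were lower (adjusted p = 5.82e-19, 8.14e-16, 1.58e-15, 1.49e-08 and 7.35e-10, and adjusted p from 0.188 to 0.197 with an estimated correlation). PPAR-alpha targets (2 higher of 29, 8 adjusted over the list alone) and circadian clock genes (2 higher and 0 lower of 19, 10 and 3 adjusted over the list alone) were higher (adjusted p = 1.49e-08 and 3.41e-05, and adjusted p from 0.188 to 0.197 with an estimated correlation).

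edgeR called 61 genes higher and 92 lower, DESeq2 314, edgeR with the replicate block 277, with the read-length class as a term 280, and with only these 2 groups 68. It called 0 within libraries 1 and 2 and 247 within libraries 3 and 4. The count was 57, 91 and 63 without Old-veh replicates 2, 3 and 4 in turn and 95, 43 and 71 without Old-JQ1 replicates 1, 3 and 4 in turn, and 20 of 35 named genes lost their call in such a run. The passing lists ran from 5.18e-32 to 0.197.

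Set against JQ1 in kidney, DCV left Cyp4a12b, Bhmt and Mdk higher, and the transporter gene Slco1a1, Hist2h2aa1 and Pck1 lower (1.55 ± 0.19, 1.53 ± 0.22, 1.53 ± 0.13, -1.59 ± 0.27, -1.36 ± 0.12 and -0.96 ± 0.11; adjusted p from 5.68e-06 to 0.00983). Mitosis (0 higher of 38, 18 adjusted over the list alone), extracellular matrix (4 higher of 31, 15 adjusted over the list alone), macrophage markers (3 higher of 16, 8 adjusted over the list alone) and cholesterol synthesis (3 higher and 0 lower of 25, 13 and 1 adjusted over the list alone) were higher with DCV and PPAR-alpha targets lower (0 higher and 3 lower of 29, 2 and 15 adjusted over the list alone; adjusted p = 1.32e-18, 3.45e-17, 6.48e-09, 1.61e-07 and 2.31e-10, and adjusted p from 0.124 to 0.209 with an estimated correlation). Interferon-stimulated genes did not pass (adjusted p = 0.784); acetyl-CoA supply passed only with the replicate block (adjusted p = 0.0593, and 0.0357 with it). Antigen presentation was higher with DCV as a list (0 of 21 past the threshold, also adjusted over the list alone; adjusted p = 0.0259, and adjusted p = 0.726 with an estimated correlation). It lost its call with the block (0.0585) and without Old-DCV replicate 1 (0.0855) or Old-JQ1 replicates 1 (0.0694), 2 (0.138) and 4 (0.155). edgeR called 143 genes, 56 higher and 87 lower, DESeq2 351, edgeR with the replicate block 362 and with the read-length class 287; within libraries 1 and 2 it called 0 and within 3 and 4 232. The count was 86, 43 and 91 without Old-DCV replicates 2, 3 and 4 in turn and 89, 231, 64 and 75 without Old-JQ1 replicates 1, 2, 3 and 4 in turn. Passing lists ran from 7.98e-26 to 0.726 or more.

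**Figure D4:**
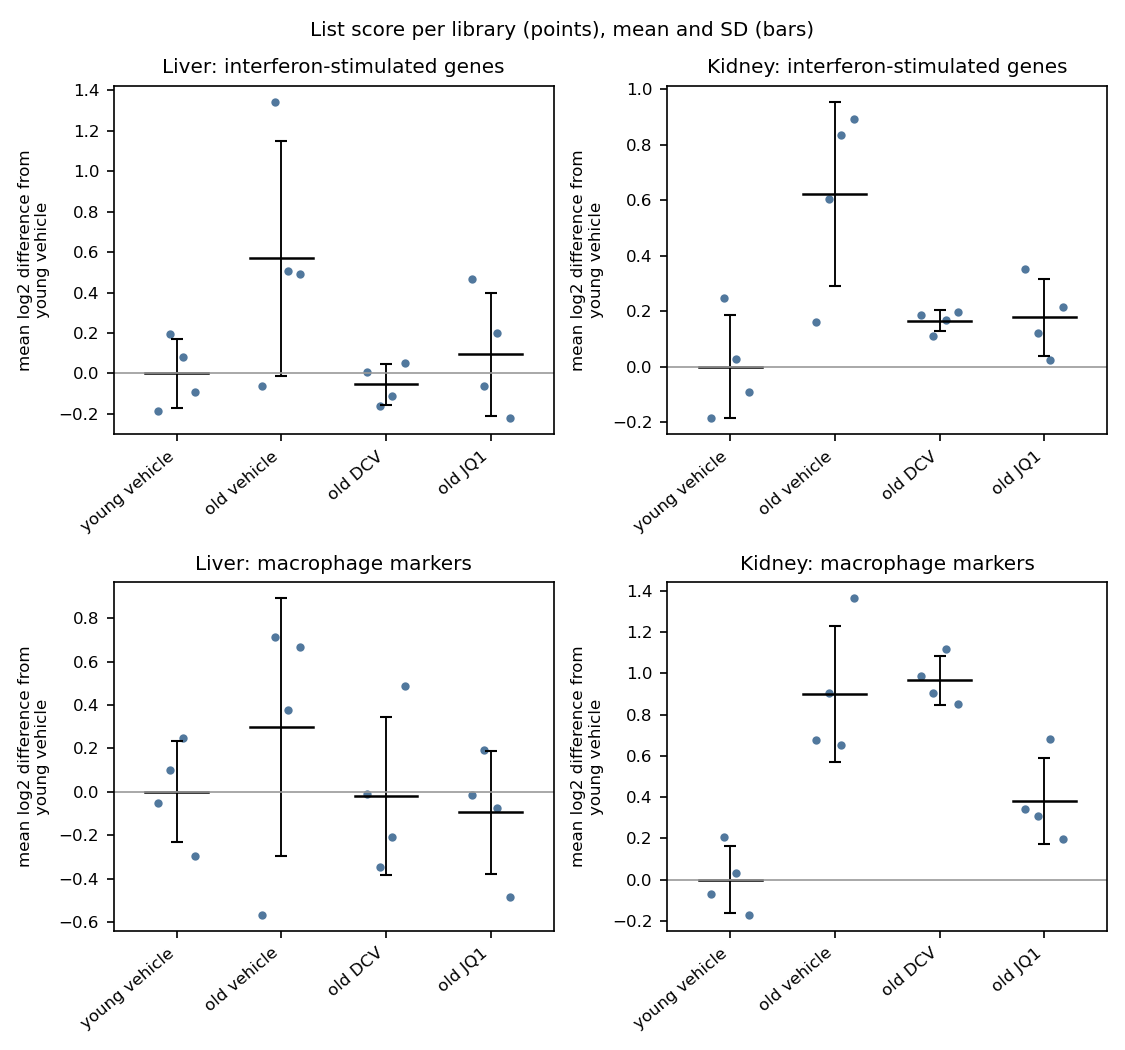
Scores of the interferon-stimulated gene and macrophage marker lists in each liver and kidney library, as mean log2 CPM minus the mean of Young-veh, with the mean and SD of each group (n = 4). In kidney the interferon score is 0.623 ± 0.332 in Old-veh and 0.167 ± 0.0381 in Old-DCV (exact permutation p = 0.114 unpaired and 0.25 within pairs).

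The effect of age was compared between kidney and liver by testing the difference itself. It was more positive in kidney for Aldh1a1, the complement genes C4b and C9, and Tcf24 (2.73 ± 0.24, 2.49 ± 0.29, 2.39 ± 0.40 and 4.55 ± 0.44; adjusted p from 1.18e-08 to 0.000896). It was more negative in kidney for Cyp51 of cholesterol synthesis, Ttr and Car3 (-1.55 ± 0.32, -1.32 ± 0.21 and -1.31 ± 0.27). Cholesterol synthesis (2 lower of 25, 17 adjusted over the list alone) had a more negative effect in kidney and acute phase and complement genes (5 higher of 28, 8 adjusted over the list alone) a more positive one (adjusted p = 4.02e-15 and 1.61e-10, and adjusted p from 0.156 to 0.421 with an estimated correlation). edgeR called 159 genes, 79 higher and 80 lower, and DESeq2 255; the count was 105 without liver Young-veh replicate 2 and 99 without liver Old-veh replicate 3. The lists that passed ran from 3.15e-29 to 0.421.

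For JQ1 the difference between tissues passed for 26 genes with edgeR, 15 higher and 11 lower, and for 78 with DESeq2; it was 16 with RLE size factors. The effect on Nat8 and Slc13a3 was more positive in kidney (1.41 ± 0.25 and 1.05 ± 0.19; adjusted p from 0.0127 to 0.0157). Fatty acid synthesis (0 lower of 26, 2 adjusted over the list alone) and acute phase genes (2 lower of 28, also adjusted over the list alone) had a more negative effect in kidney as lists (adjusted p = 0.00132 and 0.00280, and adjusted p = 0.837 for each with an estimated correlation; over the alternatives from 4.87e-05 to 0.971). The count was 15, 17 and 13 without liver Old-veh replicates 2, 3 and 4 in turn, 11, 10 and 61 without liver Old-JQ1 replicates 2, 3 and 4 in turn, 11, 8 and 11 without kidney Old-veh replicates 1, 2 and 3 in turn and 12, 12 and 12 without kidney Old-JQ1 replicates 1, 3 and 4 in turn.

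For DCV the tissues differed in 0 genes with edgeR and 0 with DESeq2, with 537 at an unadjusted p under 0.05. Interferon-stimulated genes, lower with DCV in each tissue, had a less negative effect in kidney as a list (adjusted p = 0.0374, and adjusted p = 0.812 with an estimated correlation), a direction that turned without liver Old-veh replicate 2 (0.303). The interferon-stimulated genes list lost its call in 6 of 16 runs with 1 library left out (up to 0.744, without kidney Old-veh replicate 1), without the low-count filter (0.0645) and with the replicate block (0.0584), and passing lists ran from 2.01e-07 to 0.870.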

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

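The splits were chosen before their results were seen, the comparisons by pairs, read-length classes and sides kept after. The senescence effect differed between 6 and 8 days in 35 genes, a difference tested directly. Of 100 splits drawn within the experiments, 7 gave as many, the real one included, and the highest other gave 5039. The 6 others each kept an experiment parted by senescence, so they count the senescence effect itself, a structure of the samples, and say nothing on whether chance gives 35 genes.

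The effect of age differed between kidney and liver in 159 genes. Here 3 of 100 drawn splits gave as many, the real one included, and the highest other gave 860. Of the 58 that keep the read-length classes of the kidneys balanced, as the real one does, 3 gave as many. As both others kept the kidneys parted by age, a structure of the samples as well, whether chance gives 159 genes stays open. The effect of JQ1 differed between the tissues in 26 genes, with 3 of 100 splits as large and a highest other of 305. Since the kidney numbers met the pairing rule, the count was set against the 21 drawn splits that part as many pairs. Of these, 3 gave as many. As both others kept the kidneys parted by JQ1, whether chance gives 26 genes stays open. For DCV, with 0 genes by edgeR and by DESeq2 and 537 at an unadjusted p under 0.05, each of the 100 splits reaches a count of 0 (highest other 41), so they test nothing.

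In old liver on vehicle the 10 largest genes took 18.6% of the counts of replicate 1, far from the 17.7 to 17.9% in the other libraries of the group. In old kidney given JQ1, replicate 2 had 17023 genes detected, against 16751 to 16775 in the other libraries, and the largest count total of the group, 16624573. Among 113 groups of values tested for a library that stands apart these 2 were found, and chance marks about 1 in 20. No explanation was tested for either.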

How the results depend on the processing

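The read-length class as a term, the fits of libraries 1 and 2 or 3 and 4 alone and the splits within pairs or read-length classes were chosen after the data were seen. For 1387 results on named genes, 19323 values were compared with the main ones: 17839 kept their direction and side of the threshold, 1289 lost and 195 gained the call, and 0 reversed. For 566 results on lists, 7434 of 8318 values were kept, 610 lost and 269 gained the call, and 5 reversed. Estimated correlations account for 213 of the 610. Of 288 counts of genes 195 stayed within 1.5 times the main count. The cause of the changes below was not tested, except that left-out libraries and fits of fewer groups leave fewer samples to estimate the spread.

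DESeq2 called 289, 240, 267 and 5 genes in liver for age, JQ1, DCV against JQ1 and DCV. In kidney it called 314 for JQ1, 351 for DCV against JQ1 and 2 for DCV, and for the differences 441 between days, 255 for age and 78 for JQ1. RLE size factors gave 16 for the JQ1 difference, and no low-count filter 98 for the days. With only the 2 groups compared the counts were 4198 for Qui against Pro, 27 and 56 in liver for JQ1 and DCV against JQ1, and 572 and 68 in kidney for age and JQ1. With the read-length class kidney gave 1576 for age, 280 for JQ1 and 287 for DCV against JQ1. Libraries 1 and 2 alone gave 22, 0 and 0 there, and libraries 3 and 4 alone 317, 247 and 232, and 7 for DCV. With edgeR on libraries 1 and 2, 709 and 626 genes had an unadjusted p under 0.05 for JQ1 and DCV against JQ1; DESeq2 was not run on these pairs. For siACLY#2 the list of genes higher at 8 days had adjusted p = 0.295 with an estimated correlation, and that of genes lower at 8 days 0.00350 by fry. The covariance of the siRNAs was 0.114 at a log2 CPM of at least 3.

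With the block, where numbers met the pairing rule, in kidney JQ1 gave 277 genes and DCV against JQ1 362. Besides the lists named above the replication list of kidney JQ1 lost its call (adjusted p = 0.0531). Among named genes the block ended the calls of DDX21 and PSAT1 and added EGFL7 (Qui against Pro). It ended those of Angptl4, H2-Aa and Ccna2 and added Mcm6, Nr4a1 and Utp20 (kidney JQ1), and added Srebf1, Utp20, Stab2, Aqp4 and Slc4a1 (kidney DCV against JQ1). In the differences, of which only 1 side is paired, it ended the calls of male-biased liver genes and tubular injury (0.0628 and 0.0818, DCV), Slc13a2 (JQ1) and PAPPA (days), and added Gstp1 (JQ1) and 10 named genes (days), LMNB1 and MKI67 among them. Except for CDKN1A (Sen against Qui) it changed no other call where numbers met the rule. The block gave 474 genes between days, where the numbers pair Sen with Pro but not Sen-Ctrl with Pro-Ctrl (r 0.0737 to 0.237). For age in kidney, where they pair nothing (-0.0216 to 0.464), it gave 1789. Between the siRNAs, unpaired, each library correlated best with its own number.

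With 1 library left out, the counts were 7456 to 7965 for Sen against Pro, 1137 to 2963 for Qui against Pro, 8430 to 8972 for Sen against Qui, 7221 to 8751 for Sen-siRb/p53, 9467 to 9693 for Sen-Ctrl, 6789 to 7207 for siACLY#1, 8001 to 8385 for siACLY#2 and 8878 to 9080 between the siRNAs. In liver they were 74 to 206 for age, 0 to 1 for DCV, 4 to 94 for JQ1 and 20 to 294 between the drugs, and in kidney 544 to 1266, 0 to 5, 43 to 151 and 43 to 231. The differences gave 1 to 785 for days, 99 to 181 for age, 0 to 0 for DCV and 8 to 61 for JQ1. By the rule above, directions of lists reversed in 5 such runs, given with the range of adjusted p over all runs. Mitosis in kidney reversed without Old-veh replicate 1 for age (0.0228, range 0.00782 to 0.922) and DCV (2.92e-13, up to 0.783). Oxidative phosphorylation reversed in the age difference without kidney Young-veh replicate 1 (0.885, from 0.000255). Interferon-stimulated genes did so without liver Old-veh replicate 2 in the DCV (0.303, range 2.01e-07 to 0.744) and JQ1 (0.00282, up to 0.966) differences.

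The 10 splits of 3 against 3 libraries are too few for a share under 0.05: only the real one, 1 of 10, reached 8510, 2629, 9312, 8268, 9895, 7544, 8708 and 9469 genes in the cell comparisons in the order above, and the highest other gave 0. There were 35 splits of 4 against 4. In liver 1 reached the real count for age (159, highest other 8), JQ1 (65, 2) and DCV against JQ1 (94, 1). In kidney 1 did too for age (1023, 2), JQ1 (153, 2) and DCV against JQ1 (143, 1). Unadjusted, this argues against chance in liver. But for kidney age 18 splits keep 2 libraries of each read-length class per group (highest other 2), too few for a share under 0.05. So are the 18 for JQ1 and DCV against JQ1 (highest other 2 and 1) and the 8 that part all 4 pairs (2 and 0). For DCV the real count was 0, which all 35 splits reach (highest other 21 in liver and 1 in kidney), so they test nothing.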

Other observations

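The tests of the siRNA pattern and of the interferon pattern were chosen after those results were seen; the test of carry-over was chosen before. Of the 72 genes called both for age and for JQ1 in old kidney, 68 went in opposite directions and 4 were lower in both. Independent lists would share 5.81 opposite. The Old-veh libraries enter both contrasts and give a negative relation by themselves: the covariance of the fold changes was -0.0694, against -0.0210 in simulations without effects. With the Old-veh libraries divided between the contrasts, the covariance over 6 divisions was -0.0354 on average (-0.0451 to -0.0179). In liver the 4 genes called both for age and for JQ1 (Cdhr5, Gas7, H2-T23 and Slc13a3, chosen after their values were seen) went in opposite directions, where independent lists would share 0.357 opposite. The covariance there was -0.0291, against -0.0274 in simulations, and 0.00339 over the divisions (-0.00717 to 0.0247). For age and DCV it was 0.0111 in kidney (0.00196 to 0.0232) and 0.00651 in liver (-0.000141 to 0.0221) over the divisions.

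The siRNAs against ACLY lowered it to similar TPM, yet 42.0% of the genes called with both moved in opposite directions (39.5 to 42.3% over 16 settings). A weaker dose of a shared effect would scale all genes one way, and this share argues against it as the whole cause. With the read-length class as a term 9212 genes differed between the siRNAs, against 9469 without, which argues against the class. The design holds no rescue and no further siRNA, so off-target effects of either siRNA stay open, and no biological explanation was tested.

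Pro-Ctrl replicate 2 held transcripts that are abundant in senescence: IL1B at 26.2 TPM (4620 TPM in Sen-Ctrl), MMP1 at 37.5 TPM and CXCL8 at 25.9 TPM. Over 17 such genes, all at 100 TPM or more in Sen-Ctrl, the share of the senescent level had a median of 0.703%, against a median of 0.113% for the highest other Pro-Ctrl library. The 90th percentile of the shares was 2.16 times the 10th, under the 3 times set before the test, so a carry-over of RNA or reads from senescent libraries is a candidate explanation. A few spontaneously senescent cells would leave the same trace and stay open. Without this library the senescence effect at 6 days on IL1B was 13.97 (log2) in place of 8.93, and on CXCL8 10.07 in place of 8.35; the count of genes without single libraries ranged from 9467 to 9693.

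Interferon-stimulated genes were lower with DCV in old kidney and liver as a list, but 0 of 34 passed singly, and the call is lost with an estimated correlation (adjusted p = 0.0549 and 0.384). The interferon score differed from vehicle by -0.457 in kidney (exact permutation p = 0.114, two-sided, 0.274 after adjustment over 12 tests) and by -0.623 in liver (exact p = 0.0857, adjusted 0.257), so it does not part the groups. In kidney the 16 macrophage markers had a median log2 fold change of -0.0204 (SD over markers 0.342) against -0.444 for the interferon genes. The macrophage score was 0.0653 above vehicle (lower in 2 of 4 pairs, SD of the change 0.432). The interferon change lay 0.522 lower (exact p = 0.125 within pairs, the smallest possible, adjusted p = 0.257 unpaired). The gap exceeds that SD, but was 0.319, under it, without replicates 3, so fewer macrophages stay open in kidney. In liver the medians were -0.297 (SD over markers 0.375) and -0.587, so fewer macrophages stay open. Deviations of same-numbered liver and kidney libraries had r = 0.472 and rho = 0.415 (permutation p = 0.321 and 0.186, 16 pairs). Without Old-veh 1 and 4 r was 0.254. Shared animals stay open, and an effect of ACLY inhibition is a hypothesis.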
